A study of Mus musculus with 37 samples.

How the data were processed

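DNA methylation was measured by reduced representation bisulfite sequencing in 37 mouse libraries of 10 groups. The labels mark hepatocytes and cholangiocytes as WT (wild type) or DDC, and those marked WT are called untreated here. The labels of 2 direct reprogramming libraries do not name DDC, and these are called without DDC here. Whether the WT and DDC libraries also differ in genotype is not stated in the labels. The liver groups were untreated hepatocytes, untreated cholangiocytes (the epithelial cells of the bile ducts), hepatocytes after DDC, cholangiocytes after DDC and direct reprogramming cells after DDC, with 4 libraries each. DDC is a dietary compound that injures the liver and bile ducts of mice. The other groups were mouse embryonic fibroblasts in vitro (MEF, 4 libraries), muscle in vitro (4), direct reprogramming without DDC (2), neurons in vivo (4) and neurons from induced pluripotent stem cells (neuron iPS, 3). The labels do not name the starting cell or the target cell of the direct reprogramming groups, nor the cells from which the pluripotent cells were made. They also do not say whether libraries of a group came from separate animals or cultures, so the replicates may be technical, and each p-value measures only the spread between these samples.

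Per the submitters' processing notes, reads were trimmed with Trim Galore 0.3.3 and aligned with BSMAP 2.74 to mm10. The methylation caller and its filters are not stated in the sources used here. The authors deposited 1 table per library with, for each CpG, the methylated read count and the count of all reads, as whole numbers that had not been normalized. A further deposited column holds the methylation fraction, which equals the methylated count divided by the total count to the decimals given. The counts were used here and the fraction served as a check of the columns. The tables covered 19 autosomes. Counts reached a maximum of 65535, the largest value stored.

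Depth was taken from the read counts over CpGs. It ran from 14946221 reads (neuron iPS replicate 3) to 142656391 (MEF replicate 3), with a median of 7 and 41 reads per CpG in these libraries. No molecular identifiers are recorded, so errors from depth cover counting error only and copies made by PCR are not removed.

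Counts were summed over a fixed grid of 100-bp windows. A window was tested when it held at least 3 CpGs, each with at least 10 reads in every library of its family. The liver family (20 libraries) had 62580 such windows with 352616 CpGs, and the other family (17 libraries) had 33458 windows with 190367 CpGs. Over all 37 libraries, 27051 windows passed. The median number of reads per window ran from 149 to 669 in the liver libraries and from 114 to 778 in the others. The level of a window is the percent of its reads that are methylated, and the level of a group is the mean over its libraries.

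Groups were compared by a quasi-binomial logistic model of the methylated and unmethylated counts of each window, fitted on the compared groups alone. Its dispersion was moderated across windows by the squeezeVar method of limma and held at 1 or above, and an F test gave the p-value. The port of squeezeVar was checked against limma 3.58.1. A window was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of group means of at least 20 percentage points. There were 11 comparisons of 2 groups, and a 12th model tested whether the effect of DDC differed between cholangiocytes and hepatocytes by an interaction term.

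The position of a library between a pair of reference groups was computed over defining windows, which were called between the references with a difference of at least 30 points. It is the median over these windows of the distance of the library from the first reference, in percent of the distance between the references. Windows lower and windows higher in the second reference were kept apart, and a distance of at least 5 points was required. For direct reprogramming after DDC the windows were defined on the untreated groups and scaled on the groups after DDC. For the other placements the same libraries defined and scaled the windows. Positions and mean levels were compared by exact two-sided permutation tests with Benjamini-Hochberg adjustment. The smallest p such a test can give is 0.029 for 4 against 4 or 3 against 4 libraries and 0.067 for 2 against 4.

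Windows were tied to protein-coding genes with a gene table of the matching assembly. It gives gene bodies but no strand, exons or untranslated regions. Among genes within 5 kb of a window on either side, the window was therefore assigned to the one with the nearest end. A gene body that holds the window had no priority, so a window given as outside a gene may lie in the body of another. The use of both sides departs from the rule written before, which counted only the side of the gene start. Of the windows, 83.2% in the liver family and 84.6% in the other family had a gene, which gave 12710 and 10013 genes.

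The design, the alternatives, the rule for named genes and the members of 14 gene lists were chosen before the data were examined, apart from additions named as such in the closing section. The rule ranks the called windows whose libraries do not overlap between the groups by the size of the difference. It names the first window of each of the first 10 genes in each direction. For the effects of DDC and for comparisons with reprogrammed cells it names 5 in each direction. For each gene list it names up to 4 members with the largest difference, called or not, and 1 of these is not reported here. The lists (members found in the gene table) were hepatocyte (39 of 40), cholangiocyte (40 of 40), Hippo, Notch and TGF-beta (26 of 26), immune cell (25 of 26), endothelial (20 of 20), stellate and fibroblast (27 of 27), muscle (50 of 50), neuronal (50 of 50), astrocyte and oligodendrocyte (19 of 20), pluripotency (24 of 25), germ line (19 of 20), Hox (39 of 39), other developmental transcription factors (82 of 82) and imprinted genes (26 of 31). For each list, the number of members with a called window was set against 10000 random lists matched on the number of windows per gene, in each direction. The two-sided p was adjusted over lists and directions within a comparison.

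The model was tested on simulated data with 200 changed windows per comparison. For cholangiocytes against hepatocytes it recovered 43.3% of changes of 20 points, 89.6% of 30 points and 97.0% of 50 points. For direct reprogramming after DDC against hepatocytes after DDC it recovered 23.9%, 67.2% and 95.5%. For direct reprogramming without DDC against MEF it recovered 35.8%, 71.6% and 89.4%, and for neuron iPS against neurons in vivo 41.8%, 76.1% and 89.4%. A call also needs an observed difference of 20 points, which a true change of 20 points often misses. By the adjusted p alone, 70.1%, 55.2%, 56.7% and 65.7% of changes of 20 points were recovered, in the same order. False calls made up 0.649% to 3.68% of the calls in these 4 simulations. An unadjusted p under 0.05 was reached by 6.65% to 7.75% of the unchanged windows that held both methylated and unmethylated reads. Counts at an unadjusted p are therefore too high. The shares given below are of all tested windows, and those without both kinds of reads cannot reach such a p. Such shares are therefore lower than shares of the windows with both kinds of reads, to which this range applies.

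The alternatives were coverage minimums of 5 and 20 reads, windows with a single CpG or more, a minimum difference of 30 points, a negative binomial model in edgeR 4.0.16, limma on log ratios of the counts, the replicate number as a block, and leaving out each library in turn. For positions they also included windows of 1000 bp, defining differences of 50 points, scaling on other groups or after averaging, and separate libraries for definition and scale. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3. Sex chromosomes are absent from the tables. CpGs under the coverage minimum in any library of a family were left out, so regions covered in only some groups are not reported. No pair of libraries was found to be a duplicate.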

Results

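The series measured DNA methylation at single CpGs in mouse liver cells, cultured cells and neurons, and in cells that had been reprogrammed from a different identity. Its title concerns how stable methylation laid down in development is when cells change identity. Reads over CpGs ran from 27476532 to 81972960 per library in untreated hepatocytes, from 38464265 to 124739635 in untreated cholangiocytes, from 36207980 to 61467927 in hepatocytes after DDC, from 57376530 to 74255641 in cholangiocytes after DDC and from 53951887 to 56513815 in direct reprogramming cells after DDC. They ran from 41527055 to 142656391 in MEF, from 25243334 to 81937028 in muscle, from 55530210 to 65505808 in direct reprogramming without DDC, from 30653162 to 43466225 in neurons in vivo and from 14946221 to 47827616 in neuron iPS. Coordinates are mm10, levels are group means with the SD over libraries, and differences are in percentage points.

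The liver libraries separated from the others. The first principal component (39.9% of the variance over 27051 windows) set the 20 liver libraries, at scores of -948 to -530, apart from the 17 others, at 698 to 1194. On the second component (12.6%) the muscle libraries stood alone at 1055 to 1213. On the third component (7.78%), the 4 MEF libraries (500 to 596) and the 2 direct reprogramming libraries without DDC (602 to 616) lay at one end. Cholangiocyte libraries and neurons in vivo lay at the other end, at -288 to -462 and at -507 to -584. Direct reprogramming after DDC lay with the hepatocytes on this component (168 to 211, against 189 to 273), except replicate 2 at -36.2.

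The mean level over these windows differed little between groups: 18.0% in untreated hepatocytes, 17.4% in untreated cholangiocytes, 17.3% in MEF, 16.4% in muscle, 16.6% in neurons in vivo, 17.1% in neuron iPS and 18.2% in direct reprogramming without DDC. The differences of -0.544 points (cholangiocytes minus hepatocytes), -0.920 (muscle minus MEF), -0.713 (neurons minus MEF) and 0.454 (neuron iPS minus neurons) each had an exact permutation p of 0.029, the smallest possible, and 0.0786 after adjustment over 11 comparisons. With reads summed over CpGs the last 2 reversed, to 0.949 and -1.15, muscle minus MEF was -0.207, and the exact p-values of these 4 were 0.2 to 0.8. Direct reprogramming without DDC differed by 0.864 points from MEF and 1.78 from muscle, each with an exact p of 0.067, the smallest possible for 2 against 4 libraries. None of the 11 passed after adjustment, and the remaining differences had exact p-values of 0.143 to 0.943.

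**Figure D1:**
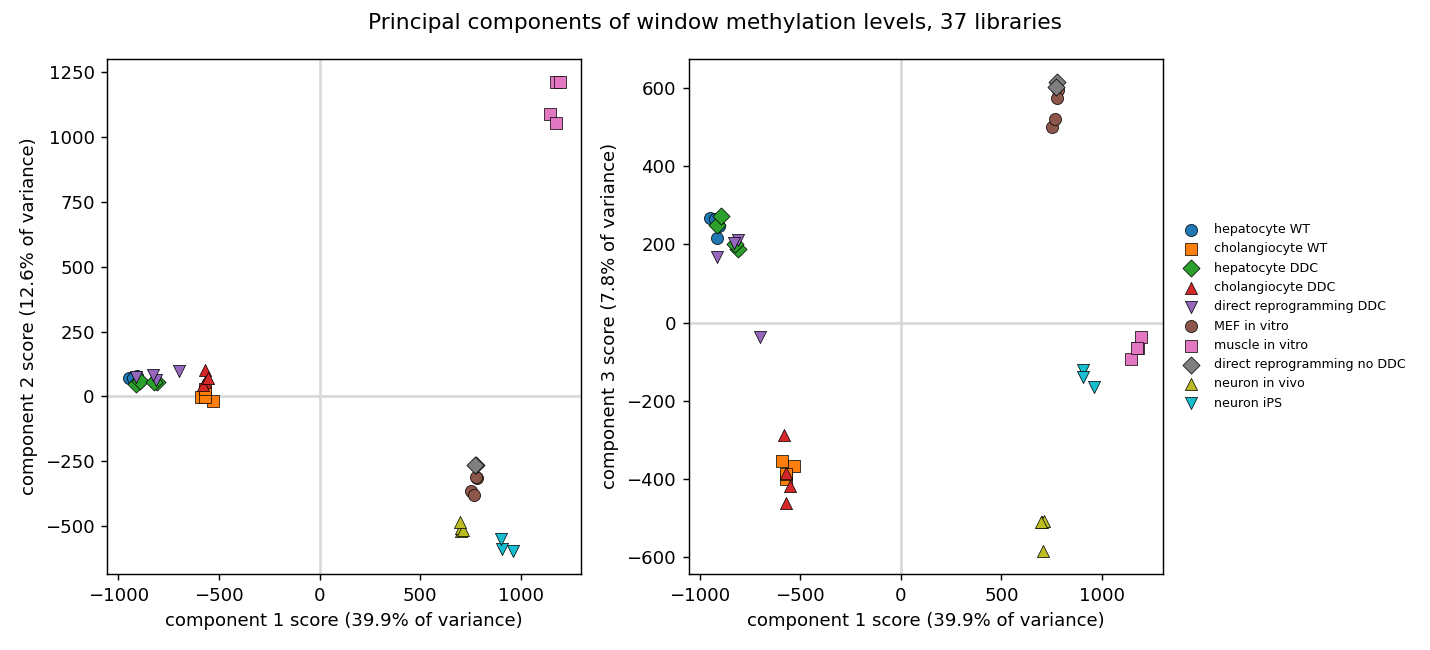
Scores of the 37 libraries on principal component 1 against component 2 (left) and component 3 (right), 1 symbol per library and 1 colour and shape per group. Liver libraries lie at -948 to -530 on component 1 and all others at 698 to 1194, and direct reprogramming after DDC replicate 2 lies at -36.2 on component 3.

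Untreated cholangiocytes and hepatocytes were compared to find methylation that tells these liver cell types apart. A window in Ttc23 (chromosome 7, 67714701 to 67714800) had a level of 96.2% ± 4.43 (SD, n = 4) in hepatocytes and 1.49% ± 0.856 (SD, n = 4) in cholangiocytes. Windows in Sorbs2, Arid5b, Msi2 and Hid1 were lower in cholangiocytes by similar amounts, at -92.6, -89.0, -88.5 and -87.6 points. The opposite direction was led by a window in Nfic (chromosome 10, 81420301 to 81420400), a member of the nuclear factor I family, at 0.765% ± 0.599 in hepatocytes and 87.0% ± 6.74 in cholangiocytes. A window in Tgfa, a ligand of the epidermal growth factor receptor (chromosome 6, 86228001 to 86228100), stood at 4.29% ± 3.55 and 79.3% ± 7.88. In all, 1336 of 62580 windows were called (2.13%), of which 567 were higher and 769 lower in cholangiocytes, in 379 and 475 genes. The median size of a called difference was 36.3 points. At an unadjusted p under 0.05 there were 10816 windows. The reads behind these named windows ran from 45 to 1364 per library.

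The lists of genes that mark each cell type held more members called lower in their own cell type than random lists did. Of 29 measured cholangiocyte genes, 10 were lower in cholangiocytes (1.72 expected from random lists, permutation p = 0.0002, the smallest these lists can give, adjusted p = 0.0056). Among them were Sox9, a transcription factor of bile duct cells, at 85.9% ± 9.63 in hepatocytes and 10.3% ± 8.96 in cholangiocytes (chromosome 11, 112785301 to 112785400), Itgb4 at 80.0% ± 12.2 and 10.9% ± 3.32, and a window 67 bp outside Cldn4, a tight junction gene, at 68.9% ± 13.2 and 7.22% ± 5.06. Another 4 of the 29 were higher in a window (adjusted p = 0.589). Of 8 measured hepatocyte genes, 4 were higher in cholangiocytes and 0 lower (0.185 expected, permutation p = 0.0004, adjusted p = 0.0056). These were Fgg and Fgb, which encode fibrinogen chains, F2, which encodes prothrombin, and Foxa3, a liver transcription factor. Fgg stood at 0.676% ± 1.35 in hepatocytes and 64.7% ± 15.8 in cholangiocytes (chromosome 3, 83012701 to 83012800), Foxa3 at 13.7% ± 11.5 and 68.6% ± 2.39, and F2 at 1.08% ± 1.54 and 41.8% ± 16.5. Adjusted over the list alone, the counts were also 10 lower cholangiocyte genes and 4 hepatocyte genes, with 5 higher cholangiocyte genes.

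The remaining lists did not pass for these cell types. Of 21 Hippo, Notch and TGF-beta genes, Smad6, Smad3 and Tead1 were lower in cholangiocytes, at -39.6, -34.2 and -26.5 points (3 genes adjusted over the list alone, adjusted p = 1). Of 81 other developmental transcription factors, 6 were higher and 2 lower, with Gata6 at 81.8% ± 18.6 in hepatocytes and 19.1% ± 9.56 in cholangiocytes. Immune cell, muscle, germ line and Hox genes had 0 called windows by the quasi-binomial model. Endothelial genes had 1 higher (Stab2) and 1 lower (Pecam1) of 15, stellate and fibroblast genes 2 lower of 22, neuronal genes 1 higher and 2 lower of 45, and astrocyte and oligodendrocyte genes 1 in each direction of 15. Pluripotency genes had 1 higher of 17 (Tbx3), and imprinted genes 1 higher of 21 (Igf2; 0 adjusted over the list alone).

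**Figure D2:**
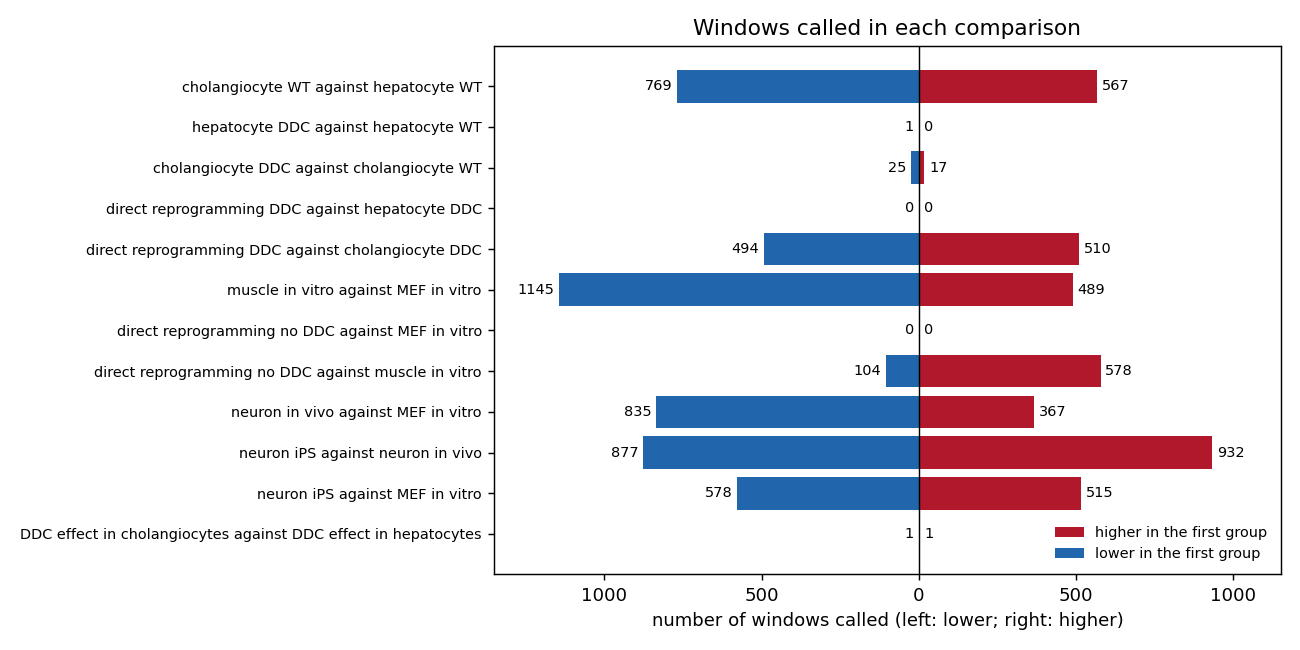
Number of windows called per comparison (horizontal axis), higher in the first group to the right and lower to the left, 1 bar pair per comparison. Cholangiocytes against hepatocytes gave 1336 calls, muscle against MEF 1634 and neurons against MEF 1202, while 1 window was called for DDC in hepatocytes and 42 in cholangiocytes (0 for both by limma), and direct reprogramming cells had 0 calls by the quasi-binomial model against hepatocytes after DDC (0 by edgeR) and against MEF (6 by edgeR).

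The comparison of DDC with no treatment asked what the compound changed within each cell type. In hepatocytes 1 window was called: in Nfic (chromosome 10, 81407701 to 81407800) the level was 28.2% ± 3.68 (SD, n = 4) without and 2.61% ± 0.902 (SD, n = 4) with DDC, over 130 to 296 reads per library. The unadjusted count was 4862 (7.77% of all tested windows, of which 54609 held both kinds of reads), edgeR called 14 windows and limma 0. Without any 1 of the 8 libraries the count was 0, except without hepatocyte DDC replicate 2, where it was 2, and the Nfic call ended in each case with a difference of similar size.

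In cholangiocytes 42 windows were called after DDC, 17 higher in 12 genes and 25 lower in 16 genes, with a median size of 41.0 points. The largest was in Spred2, which encodes an inhibitor of growth factor signalling (chromosome 11, 19979601 to 19979700): it fell from 88.5% ± 9.49 to 12.3% ± 4.31 (SD, n = 4 each), while hepatocytes stood at 93.8% ± 5.53 without and 81.4% ± 14.8 with DDC. A window in Anpep, an aminopeptidase gene (chromosome 7, 79841801 to 79841900), rose from 12.4% ± 7.01 to 61.9% ± 6.78, and one 2252 bp outside Insl3 rose from 3.22% ± 2.40 to 47.3% ± 7.24. The window assigned to Insl3 lies in the gene body of Jak3. A window 4614 bp outside the tight junction gene Cldn3 fell from 65.2% ± 4.73 to 29.7% ± 4.24. Cldn3 was the 1 of 29 cholangiocyte genes that passed (3 adjusted over the list alone, adjusted p = 1 against random lists). Endothelial genes had 1 lower adjusted over the list alone and 0 over all windows, and the other 12 lists had 0 called genes. At an unadjusted p there were 5630 windows, edgeR called 88 and limma 0. The count was 27, 24 and 17 without cholangiocyte DDC replicates 1, 3 and 4, and 17, 20 and 11 without untreated replicates 1, 2 and 3.

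By the interaction term, 2 windows were called for an effect of DDC that differs between the cell types, and these calls depended on single libraries. A window in Adra1d, an adrenergic receptor gene (chromosome 2, 131561401 to 131561500), had levels of 12.5% in hepatocytes and 13.1% in cholangiocytes without DDC and of 6.10% and 29.4% with it (difference of effects 22.8, adjusted p = 0.0394). A window near no gene (chromosome 11, 50439801 to 50439900) fell in cholangiocytes from 81.2% to 14.8% and had 75.9% and 75.5% in hepatocytes (difference -66.0, adjusted p = 0.0135). There were 4867 windows at an unadjusted p (7.78% of all tested, of which 60630 held both kinds of reads). By edgeR 24 windows were called, and by limma 0. The count was 0 without untreated hepatocyte replicate 3 or 4, hepatocyte DDC replicate 2 or untreated cholangiocyte replicate 3. It was 1 without hepatocyte DDC replicate 1 or 3, untreated cholangiocyte replicate 2 or 4, or cholangiocyte DDC replicate 2, 3 or 4. It was 0 with the replicate number as a block.

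Direct reprogramming cells after DDC were compared with both liver cell types after the same treatment, to see which pattern they carry. Against hepatocytes after DDC, 0 windows were called by the quasi-binomial model, by edgeR and by limma (smallest adjusted p 0.671). The unadjusted p was under 0.05 in 4137 windows (6.61% of all tested, of which 55304 held both kinds of reads). In simulated data of this comparison 7.45% of unchanged windows with both kinds of reads reached it, so this count is not a sign of differences. The test recovered 67.2% of simulated changes of 30 points in this comparison and 23.9% of those of 20 points (55.2% by the adjusted p alone). Against cholangiocytes after DDC, 1004 windows were called, 510 higher and 494 lower, in 319 and 327 genes. Prr5l stood at 94.4% ± 3.62 (SD, n = 4) in the reprogrammed cells and 8.98% ± 5.47 (SD, n = 4) in cholangiocytes (chromosome 2, 101805101 to 101805200). Inhbb, an inhibin subunit gene, stood at 7.13% ± 2.00 and 80.6% ± 4.20 (chromosome 1, 119419201 to 119419300). Hepatocytes after DDC had 96.1% ± 4.86 and 8.61% ± 9.31 there. The unadjusted count was 9035, and limma called 463 windows.

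In both lists of genes that mark the cell types, more members than in random lists differed from cholangiocytes in the direction of hepatocytes. Of 29 cholangiocyte genes, 10 were higher than in cholangiocytes after DDC (12 adjusted over the list alone; 1.25 expected, adjusted p = 0.0056) and 1 was lower. Itgb4 stood at 69.0% ± 4.38 against 7.38% ± 5.58 in cholangiocytes and 79.1% ± 7.28 in hepatocytes after DDC. A window in Cldn4 (chromosome 5, 134946301 to 134946400) stood at 62.7% ± 8.48 against 18.5% ± 3.51 and 71.5% ± 17.0. Of 8 hepatocyte genes, Fgg, F2 and Foxa3 were lower (3 adjusted over the list alone; 0.172 expected, adjusted p = 0.0084). F2 stood at 7.37% ± 5.85 against 53.8% ± 9.50 in cholangiocytes and 6.44% ± 8.36 in hepatocytes. Without replicate 2 the lists held 11 and 3 called genes. The other lists did not pass: 5 of 81 other developmental transcription factors were lower, among them Irx3 at 25.7% ± 6.89 against 77.7% ± 8.90, and 1 was higher, Gata6 at 82.2% ± 7.67 against 22.9% ± 5.27. Astrocyte and oligodendrocyte genes had 3 lower of 15 (adjusted p = 0.121), Hippo, Notch and TGF-beta genes 3 higher of 21, and Hox genes 1 lower of 38 (Hoxa6).

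Placed between hepatocytes after DDC (0) and cholangiocytes after DDC (100), the reprogrammed cells lay nearer to hepatocytes. At 499 windows lower in untreated cholangiocytes, in 303 genes, the mean position was 15.5 ± 19.8 (SD, n = 4), with a mean level of 58.8% against 66.2% in hepatocytes and 23.0% in cholangiocytes after DDC. At 370 windows higher in cholangiocytes, in 263 genes, it was 6.59 ± 11.7 (SD, n = 4). The exact permutation p against hepatocytes after DDC was 0.057 and 0.086 (adjusted 0.08 and 0.0935), and that against cholangiocytes after DDC was 0.029 for both (adjusted 0.057). The groups after DDC set the scale, so they lie near 0 and 100 by construction. Most groups other than cholangiocytes would separate from them at these windows. The p against cholangiocytes thus does not weigh how near the reprogrammed cells lie to hepatocytes. Replicate 2 lay at 45.1 and 24.1 and the other 3 libraries at 4.39 to 7.62 and at -0.958 to 2.07. Without replicate 2 the means were 5.65 and 0.756. At Sox9 the 4 libraries averaged 57.4% ± 27.4, against 67.7% ± 8.37 in hepatocytes and 10.9% ± 6.41 in cholangiocytes after DDC.

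**Figure D3:**
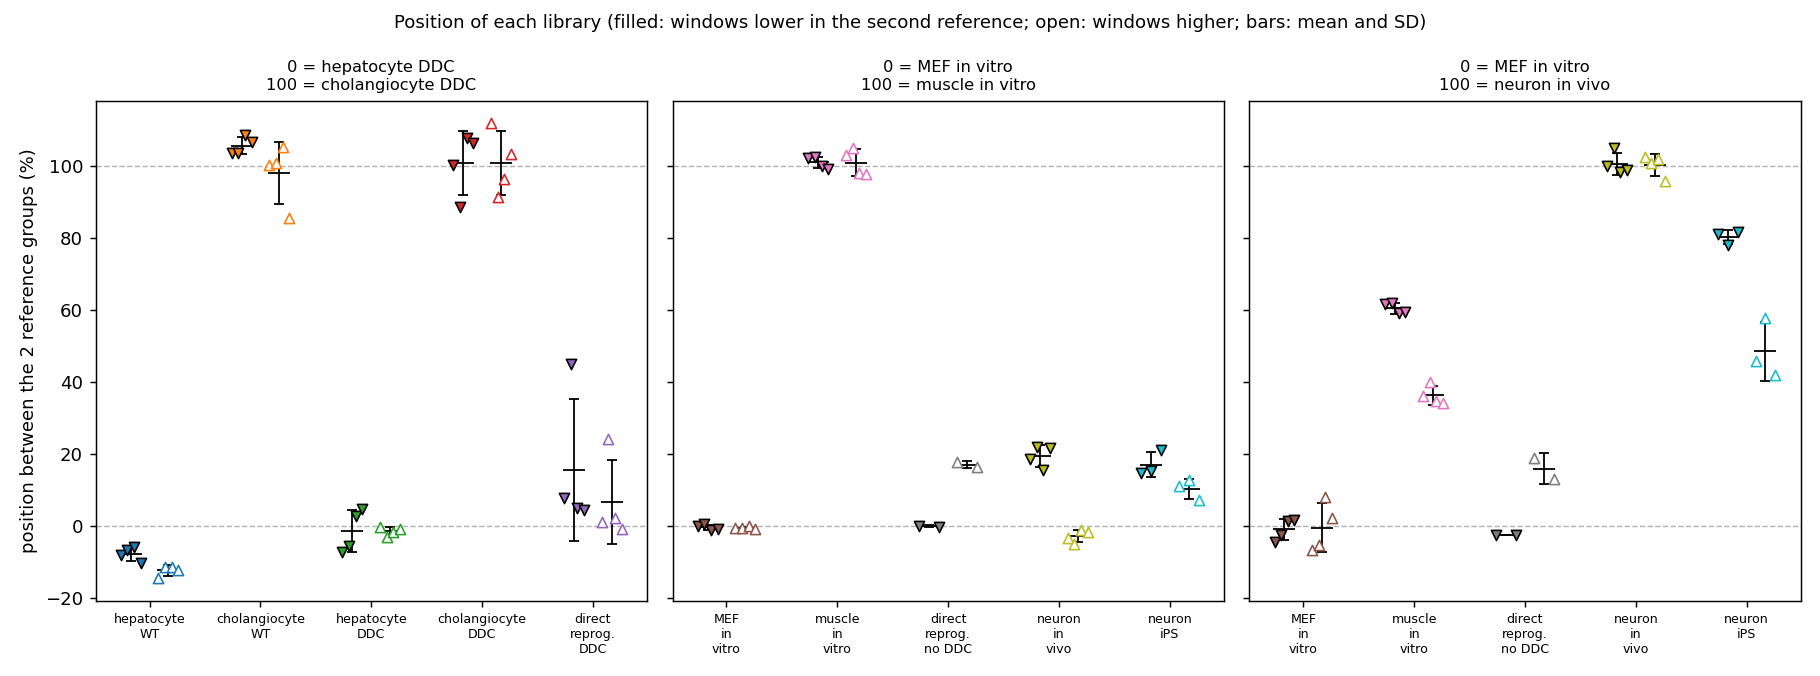
Position of each library in percent of the distance between the reference groups (vertical axis), by group; filled symbols are windows lower and open symbols windows higher in the second reference, with mean and SD. Direct reprogramming after DDC lies at 15.5 and 6.59, direct reprogramming without DDC at -0.0467 and 17.0, and neuron iPS at 80.3 and 48.5.

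Muscle and MEF in vitro were compared to find the methylation that tells these cultured cells apart. A window in Neb, which encodes nebulin of the sarcomere (chromosome 2, 52335601 to 52335700), had a level of 87.7% ± 3.08 (SD, n = 4) in MEF and 6.49% ± 6.97 (SD, n = 4) in muscle. One in Pygm, the muscle glycogen phosphorylase gene (chromosome 19, 6384501 to 6384600), had 85.6% ± 5.33 and 6.62% ± 8.80. Windows in Myh9, Col6a1 and Cacna1c were lower in muscle at -84.8, -83.4 and -83.1 points. In the other direction, Rfx4 (chromosome 10, 84759101 to 84759200) had 9.78% ± 9.53 in MEF and 91.9% ± 8.97 in muscle, and Sim2 and Fzd2 differed by 77.2 and 75.6 points. There were 1634 calls in 33458 windows (4.88%), 489 higher and 1145 lower in muscle, in 272 and 600 genes. The unadjusted count was 7801, and limma called 689 windows.

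Among the fixed lists, Hox, imprinted and germ line genes had more members called higher in muscle than random lists had. Of 32 Hox genes, 7 were higher (8 adjusted over the list alone; 1.35 expected, adjusted p = 0.0084) and 1 lower, with Hoxb2 at 8.12% ± 8.58 in MEF and 69.2% ± 11.1 in muscle and a window 4853 bp outside Hoxa13 at 1.43% ± 1.66 and 58.4% ± 24.3. Of 18 imprinted genes, 6 were higher (7 adjusted over the list alone; 0.737 expected, adjusted p = 0.0056) and 2 lower. Grb10 stood at 2.78% ± 3.68 in MEF and 46.2% ± 25.9 in muscle (chromosome 11, 12025601 to 12025700). Of 10 germ line genes, 3 were higher (3 adjusted over the list alone; 0.157 expected, adjusted p = 0.0131), with Slc25a31 at 75.3% ± 6.97 and 99.7% ± 0.660. Muscle genes did not pass as a list: 4 of 21 were lower (5 adjusted over the list alone, adjusted p = 0.609), among them Neb, Pygm and Cav3, and 1 was higher. Other developmental transcription factors had 13 higher and 7 lower of 77 (adjusted p = 0.462 for the higher), Hippo, Notch and TGF-beta genes 4 lower and 1 higher of 20, neuronal genes 4 lower of 43, stellate and fibroblast genes 1 higher and 2 lower of 14, and pluripotency genes 1 higher of 16 (Prdm14).

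The 2 direct reprogramming libraries without DDC were compared with MEF and muscle, although the labels do not say from which cell they came. Against MEF, adjusted over all tested windows, 0 were called by the quasi-binomial model and by limma, and 6 by edgeR (smallest adjusted p 0.428). The unadjusted p was under 0.05 in 2698 windows (8.06% of all tested, of which 31271 held both kinds of reads). Of the unchanged windows with both kinds of reads in its simulation, 6.65% reached it. The real share was thus higher than the simulated one. In simulated data of this comparison 71.6% of changes of 30 points were recovered. Against muscle there were 682 calls, 578 higher in 337 genes and 104 lower in 57 genes. Pygm stood at 76.2% ± 8.97 and Col6a1 at 76.6% ± 7.71 (SD, n = 2), against 6.62% and 4.21% in muscle. Hoxb2 stood at 6.61% ± 0.640 and Rfx4 at 18.4% ± 1.69, against 69.2% and 91.9% in muscle. The count rested on both libraries: it was 0 without replicate 1 and 0 without replicate 2, which leaves a single library, and 432 without muscle replicate 3. Limma called 1 window and the unadjusted count was 6316.

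None of the 14 lists passed against muscle. Muscle genes had 4 higher and 1 lower of 21 (5 higher adjusted over the list alone, adjusted p = 0.378), stellate and fibroblast genes 3 higher and 1 lower of 14, other developmental transcription factors 6 higher and 4 lower of 77, and neuronal genes 3 higher of 43. Adjusted over the list alone, 6 imprinted and 4 Hox genes were lower.

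Between MEF (0) and muscle (100), these cells lay at -0.0467 ± 0.174 (SD, n = 2) at 827 windows lower in muscle, in 455 genes, with an exact permutation p of 0.667 against MEF and 0.067 against muscle. At 285 windows higher in muscle, in 154 genes, they lay at 17.0 ± 0.890 (SD, n = 2), with mean levels of 26.2% in MEF, 34.6% in the reprogrammed cells and 69.4% in muscle and an exact p of 0.067 against each. The smallest p possible with 2 libraries is 0.067, so neither difference can pass 0.05. The sign of the first value changed under other settings, which placed it between 0.434 and 1.80. With p-values adjusted over each set of defining windows alone, 13 of the 827 and 6 of the 285 were called against MEF. Against muscle 805 and 235 were called. The MEF and muscle libraries also chose these windows.

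Neurons in vivo and MEF were compared to find windows that separate neurons from fibroblasts. A window in Rbfox3, which encodes the neuronal nuclear protein NeuN (chromosome 11, 118898501 to 118898600), was higher in neurons, at 60.5% ± 4.71 (SD, n = 4) against 11.3% ± 5.54 (SD, n = 4) in MEF. Bcl11b, a transcription factor of cortical neurons, was lower at 11.1% ± 7.98 against 70.4% ± 10.3 (chromosome 12, 107928401 to 107928500), as was Gria1, a glutamate receptor gene, at 46.8% ± 6.71 against 93.5% ± 4.40. Ptprm, Myh9 and Sox8 were lower in neurons at -80.2, -79.6 and -78.9 points. There were 1202 calls (3.59%), 367 higher in 157 genes and 835 lower in 470 genes. The unadjusted count was 6590, and limma called 715 windows. Imprinted genes passed as a list with 5 of 18 higher (6 adjusted over the list alone; 0.359 expected, adjusted p = 0.0112), among them Grb10 at 48.6% ± 7.05 against 2.78% ± 3.68, and 1 lower. Hox genes had 6 lower of 32 (adjusted p = 0.392), such as Hoxd4 at 4.11% ± 2.77 against 54.3% ± 7.74. Other developmental transcription factors had 17 lower of 77 (10.5 expected, adjusted p = 0.407), and neuronal genes 3 higher and 5 lower of 43 (adjusted p = 0.853 and 0.906).

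Neuron iPS were compared with neurons in vivo to ask how far the cells derived from pluripotent cells match. Windows in some transcription factor genes were higher in the derived cells: a window in Runx3 (chromosome 4, 135155301 to 135155400) had a level of 75.8% ± 3.93 (SD, n = 3) against 8.02% ± 9.34 (SD, n = 4), and one in Gata2 (chromosome 6, 88200201 to 88200300) had 51.8% ± 12.1 against 7.52% ± 3.51. A window in Sox2, a factor used to induce pluripotency (chromosome 3, 34650701 to 34650800), had 50.5% ± 12 against 0.532% ± 1.06, and one in Klf4, another such factor (chromosome 4, 55530901 to 55531000), 42.7% ± 15.7 against 1.33% ± 2.67. The 8 called windows of these 2 genes also took a larger share of all reads in neuron iPS, by a median factor of 3.98 over neurons in vivo, against 0.908 at the 924 other windows called higher. Slfn9 and Unc5b were also higher, at 64.7 and 63.4 points. Windows in Bcl11b and Vps13b were lower, at -54.4 and -62.4 points. There were 1809 calls (5.41%), 932 higher in 519 genes and 877 lower in 297 genes. The unadjusted count was 7771, and limma called 857 windows.

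Of the lists, 3 passed in this comparison. Of 77 other developmental transcription factors, 20 were higher and 0 lower (20 adjusted over the list alone; 9.58 expected, adjusted p = 0.0168), Sox2 among them. Of 14 stellate and fibroblast genes, 5 were higher (5 adjusted over the list alone; 0.841 expected, adjusted p = 0.0168) and 1 lower, with a window 961 bp outside Twist2 at 83.6% ± 4.23 against 39.1% ± 13.9. Of 18 imprinted genes, 9 were lower (9 adjusted over the list alone; 0.630 expected, adjusted p = 0.0056) and 3 higher. Grb10 stood at 3.12% ± 2.38 against 48.6% ± 7.05 and Gnas at 28.8% ± 10.7 against 69.4% ± 11.1. Without replicate 3, the shallowest library, the counts were 23, 5 and 8. Muscle genes had 5 higher of 21 (adjusted p = 0.0896), cholangiocyte genes 5 higher of 24 (0.133), pluripotency genes 4 higher of 16 (0.144), Sox2 and Klf4 included, and immune cell genes 2 higher of 6 (0.269). Neuronal genes had 3 higher and 2 lower of 43, Hox genes 1 higher of 32 (Hoxa9) and germ line genes 1 in each direction of 10.

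Against MEF, neuron iPS had 1093 called windows (3.27%), 515 higher in 290 genes and 578 lower in 331 genes. Ptprm and Nxn were lower, at 2.07% ± 2.44 and 7.19% ± 7.31 (SD, n = 3) against 89.0% ± 7.55 and 92.9% ± 5.80 (SD, n = 4), and Sh3d21 was higher, at 84.7% ± 9.51 against 11.9% ± 4.67. Bcl11b and Gria1 were lower by windows at -55.6 and -49.8 points. None of the 14 lists passed: stellate and fibroblast genes had 4 higher of 14 (4 adjusted over the list alone, adjusted p = 0.0672), muscle genes 4 higher of 21 (0.109) and Hox genes 5 lower of 32 (0.226). The unadjusted count was 6080, limma called 364 windows, and the count was 643 and 569 without neuron iPS replicates 1 and 2.

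Between MEF (0) and neurons in vivo (100), neuron iPS lay at 80.3 ± 1.86 (SD, n = 3) at 541 windows lower in neurons, in 309 genes, with mean levels of 68.6% in MEF, 36.0% in neuron iPS and 24.6% in neurons. At 165 windows higher in neurons, in 72 genes, they lay at 48.5 ± 8.18 (SD, n = 3), with 35.9%, 54.7% and 75.4%. Each set differed from both references at an exact permutation p of 0.029, the smallest possible (adjusted 0.057). The reference libraries chose and scaled these windows, so they lie near 0 and 100 by construction. Most other groups would separate from them too, so this p does not weigh how far neuron iPS match neurons. With p-values adjusted over each set of defining windows alone, 371 of the windows lower in neurons were called against MEF and 165 against neurons. Of those higher, 76 and 80 were called. This rule is looser than the adjustment over all tested windows. On the same scale muscle lay at 60.5 ± 1.52 and 36.3 ± 2.67 (SD, n = 4). With windows defined on MEF and neuron replicates 1 and 2 alone the position at the higher windows was 18.0, and with replicates 3 and 4 it was 61.6.

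**Figure D4:**
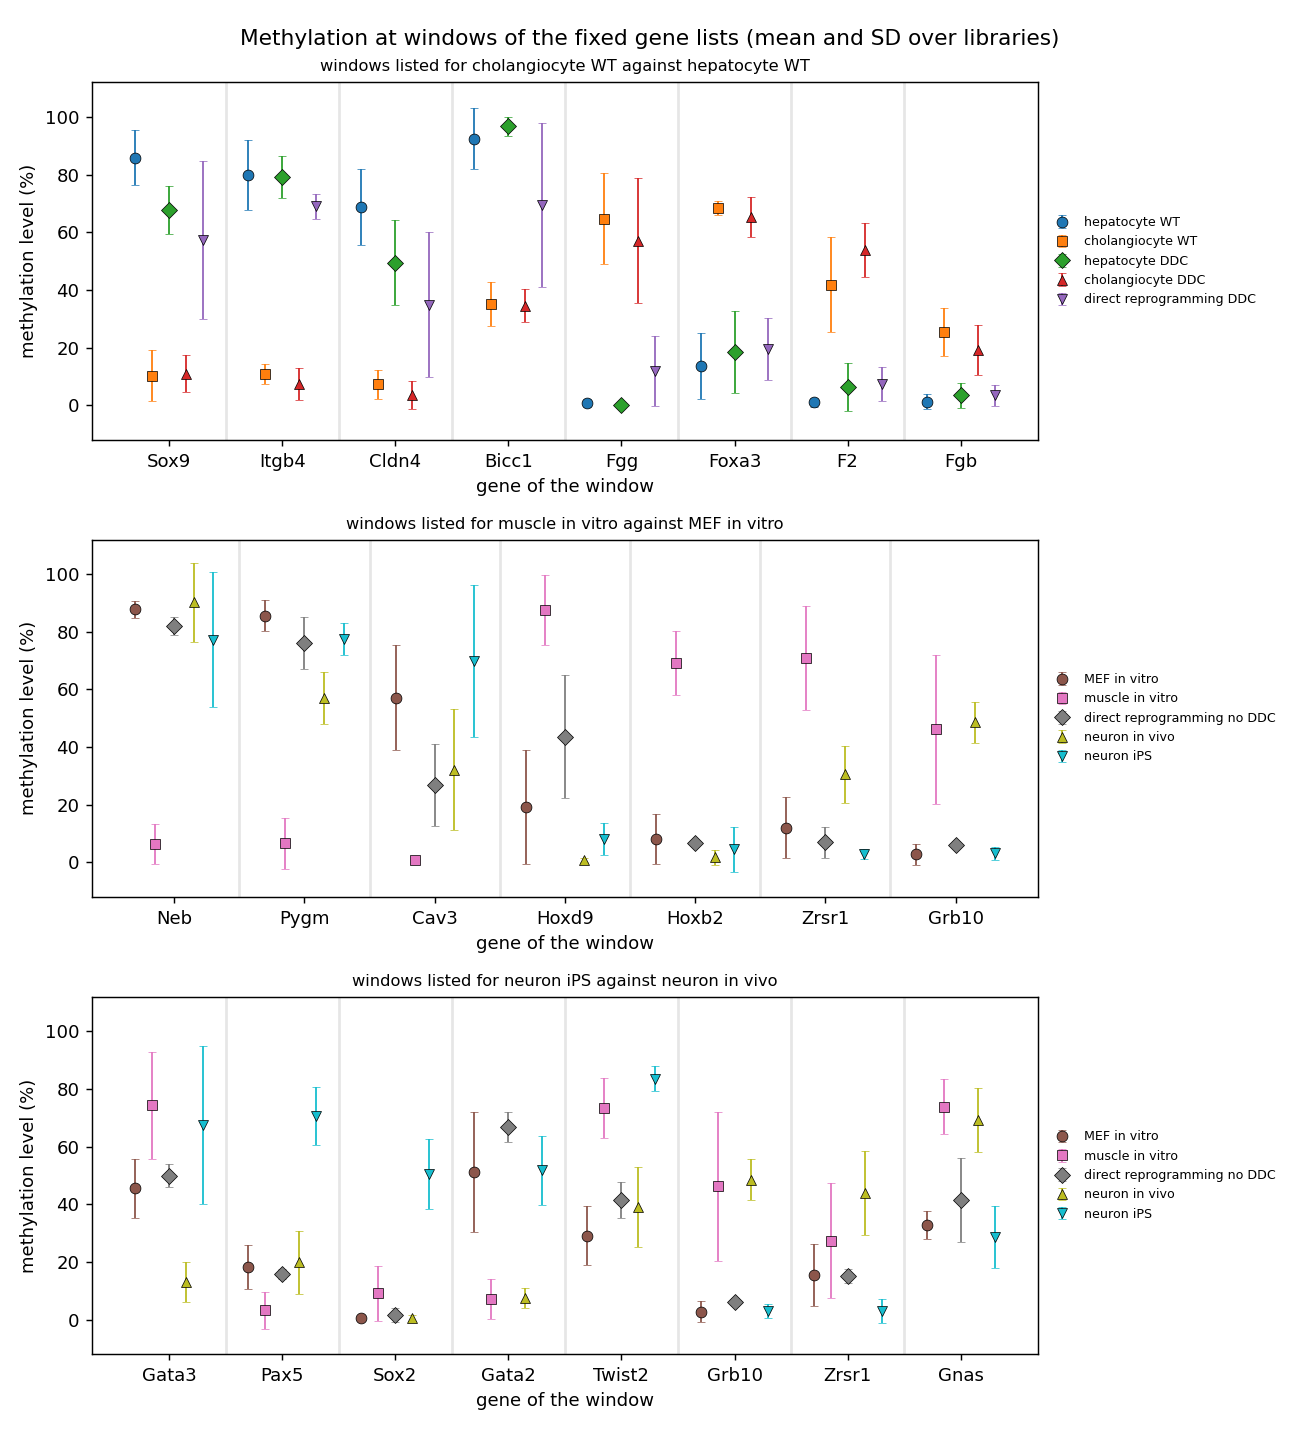
Methylation level in percent (vertical axis) at windows of the fixed gene lists, mean and SD over the libraries of each group, for liver (top), muscle and MEF (middle) and neuron comparisons (bottom). Itgb4 and Fgg show the reprogrammed cells after DDC near hepatocytes, Neb and Hoxb2 the reprogrammed cells without DDC near MEF, and Grb10 and Sox2 neuron iPS apart from neurons in vivo.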

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

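The tests for a share of cholangiocyte DNA, for the choice of windows on MEF and for a share of muscle cells were chosen only after the results they weigh were seen.

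Direct reprogramming after DDC replicate 2 stood far from the other 3 libraries of its group, at a position of 45.1 (others 4.39 to 7.62) at windows lower in cholangiocytes and 24.1 (others -0.958 to 2.07) at windows higher. Chance flags about 1 in 20 groups. Of the 18 values tested, which were positions, mean levels and read depths, 2 stood out, both positions of this library. Low depth is argued against, since its median was 18 reads per CpG and those of the others 17 to 18. A share of cholangiocyte DNA would place both window sets alike, but scaled after averaging the positions were 48.0 and 23.6, a difference of 24.4 points (95% bootstrap interval 19.7 to 29.1), so such a share is not the whole cause. DNA of other non-hepatocyte cells cannot be told apart from it: positions were 43.6 at 13 windows low in cholangiocytes alone and 43.9 at 76 windows low also in non-liver cells, a difference of 0.381 points with a bootstrap interval too wide to decide (-39.2 to 31.7 for the reverse difference), and more complete reprogramming of this sample was not tested.

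Direct reprogramming without DDC lay at 17.0 at windows higher in muscle and near 0 at windows lower in muscle. The choice of windows on the MEF libraries is argued against, because the position was 15.8 (libraries 13.6 and 17.9) when MEF and muscle replicates 3 and 4 defined the windows and replicates 1 and 2 set the scale. A share of muscle cells would move both window sets alike, but they differed by 17.1 points. A general gain of methylation against MEF remains as a candidate explanation for part of it: matched windows that do not differ between muscle and MEF gained 4.44 points (3.71 to 5.14), against 8.42 (bootstrap interval 7.41 to 9.42) at the 285 windows higher in muscle. The gain was not limited to the muscle scale: between MEF and neurons in vivo the same libraries lay at 15.9 ± 4.21 (SD, n = 2) at windows higher in neurons and at -2.60 at windows lower. The reprogramming itself stays open as a biological explanation for the rest and was not tested.

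Of 18 imprinted genes, 9 were called lower in neuron iPS than in neurons in vivo and 3 higher. A general loss of methylation is argued against, since windows matched on their level in neurons differed by a median of 5.70 points (-2.45 to 14.6 over 1000 draws), against -24.3 over the 35 imprinted windows above 20%. The low depth of replicate 3 is argued against by the 8 genes called without it. Sequence variants at single CpGs are argued against because 98.1% of the 104 CpGs in the 20 called windows fell by 10 points or more. A loss of methylation at imprinted regions during derivation or culture of the cells may be the reason, as a hypothesis that was not tested. Against MEF, 2 of the 18 genes were lower in neuron iPS and 1 higher (adjusted p = 1 for each), and Grb10 stood at 2.78% in MEF and 3.12% in neuron iPS.

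Within groups of 4, a named window counted here when 1 library stood apart from the other 3. This held for 18 of 147 windows in untreated hepatocytes, 15 in untreated cholangiocytes, 17 in hepatocytes after DDC, 5 in cholangiocytes after DDC and 20 in direct reprogramming after DDC, 13 of them through replicate 2. Among 186 named windows of the other family it held for 5 in MEF, 29 in muscle and 16 in neurons in vivo. The chance rate of about 1 in 20 groups does not apply to levels near 0%. There, 3 libraries at 0% and 1 slightly above always count as 1 library apart. Untreated hepatocytes were such a case at the windows of Arid2 (0% to 2.27%) and Hrk (0% to 4.55%). How many counted windows are of this kind was not tested, so these counts do not show an excess of outlying libraries.

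By the interaction term, the effect of DDC in cholangiocytes minus that in hepatocytes was 22.8 points at the Adra1d window and -66.0 points at the window near no gene on chromosome 11. Splits of the samples do not exclude chance for this count of 2, as 6 of 100 splits gave as many and the highest other gave 14, several times the real count, which may point to a structure of the samples that was not tested. The count of 1336 (cholangiocytes against hepatocytes) was reached by 1 of 35 splits, the real one, and the highest other gave 1. This also held for 42 (cholangiocytes after DDC against untreated) and 1004 (direct reprogramming after DDC against cholangiocytes after DDC). The same holds for 1634 (muscle against MEF), 1202 (neurons against MEF), 1809 (neuron iPS against neurons) and 1093 (neuron iPS against MEF), where the highest other split gave 0. A share of 1 of 35 is the smallest that these splits can give. Every other split mixes the 2 groups, which widens the spread within each, so few calls there are likely wherever the groups differ. The splits thus argue against chance to this extent but do not exclude it, and by limma the count of 42 was 0. For hepatocytes after DDC against untreated, 1 of 35 splits, the real one, reached the count of 1 and the highest other gave 0, but leaving out any 1 library ended the call, so chance is left open. For direct reprogramming after DDC against hepatocytes after DDC, 35 of 35 splits reached the real count of 0 and the highest other gave 1.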

How the results depend on the processing

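The definition of windows on reference replicates 3 and 4 and the gene list counts without doubted libraries were chosen only after the data were seen. In 7 comparisons the counts of calls moved with the choices of reads and CpGs that alter how many windows are tested. In the order cholangiocytes against hepatocytes, direct reprogramming after DDC against cholangiocytes after DDC, muscle against MEF, direct reprogramming without DDC against muscle, neurons against MEF, neuron iPS against neurons and neuron iPS against MEF, they were 2173, 1571, 3058, 1170, 2153, 3043 and 1846 at a minimum of 5 reads and 566, 475, 475, 202, 356, 577 and 328 at 20 reads, where fewer windows are covered. With 1 CpG or more per window they were 5095, 3686, 6684, 2372, 4244, 4342 and 3119. The effect of DDC gave 16 in cholangiocytes at 20 reads and 222 with 1 CpG, 2 in hepatocytes with 1 CpG, and for the interaction 0 at 20 reads and 1 with 1 CpG. At 30 points the counts were, by construction, lower: 869 for cholangiocytes against hepatocytes, 664 for direct reprogramming after DDC against cholangiocytes after DDC, 706 for neurons against MEF, 791 and 683 for neuron iPS against neurons and MEF, 0 for DDC in hepatocytes and 1 for the interaction. By edgeR the counts were 14 and 88 for DDC in hepatocytes and cholangiocytes, 6 for direct reprogramming without DDC against MEF and 24 for the interaction. By limma they were 0, 0 and 0 for both effects of DDC and the interaction, 463, 689, 1, 715, 857 and 364 for the others in the order above from direct reprogramming after DDC on. The cause was not tested for either tool.

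With the replicate number as a block the counts were 538 (cholangiocytes against hepatocytes), 453 (muscle against MEF), 89 (neurons against MEF) and 0 for every other comparison. The labels do not say whether the numbers pair the samples. Only untreated cholangiocytes and hepatocytes had 4 of 4 libraries correlated best with their own number (r 0.0950 to 0.139). This is a hint from the data and not from the design, so pairing of these 2 groups is left open. Positions of neuron iPS with the block were 82.2 and 49.9 (exact sign-flip p = 0.25, the smallest possible).

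Leaving out 1 library at a time gave 1166 to 1308, 0 to 2, 11 to 33, 0 to 0, 720 to 1143, 1114 to 1680, 0 to 0, 0 to 659, 911 to 1292, 1441 to 1797, 569 to 1039 and 0 to 2 calls for the 12 comparisons in the order of the plot of calls. Where 1 reprogrammed library was left, it was assumed to vary like the other group. Positions ran from 5.65 to 19.2 and from 0.756 to 9.11 (direct reprogramming after DDC), from -0.17 to 0.0765 and from 16.4 to 17.7 (without DDC) and from 79.6 to 81.4 and from 43.9 to 51.7 (neuron iPS). Gene list counts without the doubted libraries were 3, 11, 5, 23 and 8. Of the 154 named windows, leaving out a library kept direction and call in 1066 cases, ended the call in 111, added it in 3 and reversed 0, and the other alternatives gave 663, 145, 4 and 0.

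The position of direct reprogramming after DDC against hepatocytes reached an exact p of 0.029 at 16.2 (5 reads), 17.7 (1000-bp windows), 6.76 (20 reads) and 17.6 (scaled on the untreated groups). That of direct reprogramming without DDC at windows lower in muscle reversed its sign, at 0.553 (5 reads), 0.434 (1000-bp windows), 0.83 (50 points) and 1.80 (scaled after averaging), and the cause was not tested; replicates 1 and 2 alone defined 0 windows for it. Neuron iPS lay at 73.5 and 18.0 with windows defined on replicates 1 and 2 and at 85.3 and 61.6 on 3 and 4, with too few libraries to pass. With reads summed over CpGs the difference in mean level was -1.75 (cholangiocytes against hepatocytes), -0.207 (muscle against MEF) and, reversed, 1.17 and -0.230 (DDC in hepatocytes and cholangiocytes), 0.949 (neurons against MEF) and -1.15 (neuron iPS against neurons), and for the last 0.153 at 5 reads. The cause was not tested.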

Other observations

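The test for extra copies of reprogramming genes and the summary of imprinted windows over all groups were chosen only after the data were seen. The imprinted windows that were lower in neuron iPS differed between other groups as well. They lie in Mcts2, Nnat, Gnas, Nap1l5, Magel2, Grb10, Zrsr1, Igf2r and Impact. Of the 20 windows, 15 were covered in all 37 libraries, with mean levels of 41.0% ± 2.02 (SD, n = 4) in neurons in vivo and 9.41% ± 2.01 (SD, n = 3) in neuron iPS. Liver groups stood near the neurons, at 37.2% ± 3.33 in untreated hepatocytes, 40.1% ± 0.773 in untreated cholangiocytes, 42.1% ± 4.34 and 44.0% ± 4.04 in these cells after DDC and 41.0% ± 2.52 in direct reprogramming after DDC. MEF stood at 17.8% ± 6.47, direct reprogramming without DDC at 17.7% ± 3.55 (SD, n = 2) and muscle in vitro at 42.9% ± 12.2.

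Hepatocytes after DDC were placed on windows that separate untreated cholangiocytes from untreated hepatocytes, under the hypothesis that DDC moves hepatocyte methylation towards that of cholangiocytes. Each untreated library was placed on windows defined without it. At windows higher in cholangiocytes, hepatocytes after DDC lay at -1.52 ± 1.33 and untreated ones at -10.5 ± 1.15 (SD, n = 4 each), a difference of 8.94 points with an exact permutation p of 0.029 and no overlap. At windows lower in cholangiocytes the positions were -1.41 ± 6.01 and -4.59 ± 2.11, a difference of 3.17 points with an exact p of 0.371. The libraries after DDC also set the scale and so lie near 0, while untreated libraries chose the windows. A deviation shared by the untreated group thus cannot be told apart from an effect of DDC. A small shift may exist at windows that gain methylation, but this placement cannot settle it. The other direction does not show one beyond the spread.

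The gains at Sox2 and Klf4 in neuron iPS came with more reads. Among windows tied to Pou5f1, Sox2, Klf4 and Myc, 8 were called higher than in neurons in vivo, 5 in Sox2 and 3 in Klf4. Their share of reads was a median of 3.98 times that in neurons in vivo, above all 10000 draws of 8 other windows called higher, where the median was 0.908. The called windows of each gene are adjacent and so not independent, whereas the draws took windows at random. The place among the draws therefore overstates how unusual the share is. At Sox2 the factor was 3.09 at the called window from 34650701. At uncalled Sox2 windows it was 0.621 (from 34649801), 0.611 (from 34649901), 0.862 (from 34656601) and 3.58 (from 34651101). The last of these had a level of 16.5% in neuron iPS and 0.299% in neurons in vivo. At Klf4 the factor was 4.33 at the called window from 55530901 and 1.13 at the uncalled one from 55532201. Over MEF the factor was 3.05 at the window of Sox2 from 34650701. At the 3 called windows of Klf4 it was 5.72 (from 55530701), 3.89 (from 55530801) and 1.60 (from 55530901). Methylated extra copies of these genes, such as vectors used to induce pluripotency, may account for the gain at these windows. The labels do not say how pluripotency was induced, no window of Pou5f1 was covered well enough to be tested, and no window of Myc was called.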
